A study of Mus musculus with 7 samples.

How the data were processed

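Gene expression was measured by RNA-seq in tissue dissected behind the last somite of E9.5 mouse embryos, in 3 wild-type and 4 Smchd1-null samples per the sample labels; the design text of the series names 3 null samples. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.12, edgeR and the genome build mm10 were used; the order of these steps, the counting tool, its strand setting and the annotation are not given in the sources used here. The table deposited by the authors holds log2 RPM values (reads scaled to a library denominator) for 25965 rows in 7 library columns, per the file headers. Its columns name a genotype but no sample number, so each column was assigned to a group only, and libraries were lettered in file order. The numbers in the column names are not explained in the sources used here. Of gene names shared with GENCODE M21 on the same chromosome, 99.6% overlapped in coordinates, so positions are given in mm10.

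Whole reads could be recovered, since all checked values below 1000 reads were whole multiples of 1 read within 0.01, and a gene with no read was listed at 0.9 read. The denominators were 59.2 to 68.2 M reads, of which 28.8% to 37.9% were reads in listed genes. A gene with no read in a library is below 0.044 to 0.0507 RPM, the limit that a count of 0 allows at 3 reads, for counting error only. All 13 mitochondrial rows had no reads in any library. Libraries of the same group differed by more than sampling noise, with chi-square per degree of freedom from 7.97 to 21.8, so none was counted as a duplicate. The labels do not state whether each library is a separate embryo, and p-values measure the spread between these libraries.

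Genes with a log2 value above 0 in at least 3 libraries were kept, which gave 13997 genes, of them 496 X-linked and 13500 autosomal. Genotype was tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a prior trend and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera, which compares the genes of a list with all other genes tested. It used a preset correlation of 0.01, two-sided, adjusted over the 23 of 24 lists with at least 3 genes kept, and the Y-linked list had 0. The X-linked shift and list means were compared by two-sided exact permutation over 35 splits. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

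The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named Smchd1 and Xist, up to 8 higher and 8 lower autosomal genes by fold change and 8 X-linked genes by p, each past the threshold with a mean log2 value of at least 1 and no overlap between groups. From each list it named up to 5 passing members (10 for Hox genes and protocadherins), or the 2 with the smallest p where none passed. Members passing only when adjusted over the list alone, the X-linked genes called after scaling, and 4930433N12Rik were named after their values were seen. The alternatives fixed in advance were other filters, a pseudocount of 1, autosomal median centring, cyclic loess, quantile normalization, other priors, array weights, a minimum fold change, other set tests and leaving out each library. Blocks on the numbers in the column names, voom on the recovered reads, combinations with centring, and estimated correlation without the filter were chosen after seeing the data. The planned count test with another tool was set for a file of raw counts and was not run, although whole reads could be recovered and were fitted with voom.

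The fit was tested on simulated data with 13997 genes, 50 of them changed at each size. On the deposited scale it recovered 32% of changes of 0.5 log2, 80% of changes of 1, 98% of changes of 2 and 100% of changes of 3, and 103 of its 258 calls were unchanged genes. After centring it recovered 40%, 78%, 92% and 100%, and 11 of its 166 calls were unchanged genes. The deposited scale thus made more false calls in the simulation than the 0.05 threshold allows, and the centred scale slightly more. The simulation was a single run with noise drawn independently for each gene. It also held far more changed genes than the real comparison called, which was 6 as deposited and 8 after centring. Its recovery therefore need not carry over to the real data.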

Results

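RNA-seq was performed on tissue from the posterior end of E9.5 female FVB/N mouse embryos, taken behind the last visible somite, a piece that the labels call postsomitic mesoderm and the series title presomitic mesoderm. The 3 wild-type libraries were compared with 4 libraries from embryos homozygous for MommeD1, a null allele of Smchd1 per the labels. Smchd1 encodes a chromosomal protein of the SMC family with a known role in X-chromosome inactivation. The table listed 25965 genes, with 22137823 to 23847381 reads in listed genes in the null libraries and 19622596 to 23548995 in the wild-type libraries. These reads were 36.0% ± 1.56 (SD, n = 4) of the denominator of the deposited values in the null libraries and 32.6% ± 4.77 (SD, n = 3) in the wild-type libraries. The deposited values therefore carried a shift, with the median log2 fold change of all 13997 tested genes at 0.16. Values relative to the autosomal median of each library are called centred and are given beside the deposited ones for the named genes. An SE or adjusted p printed in the same parenthesis as the deposited and centred change of a gene belongs to the deposited change. Libraries are lettered within each group, since the column names do not say which numbered sample each one is.

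The comparison of null with wild-type tissue asked which genes respond to loss of Smchd1. Smchd1 itself was lower in every null library, with 1922 to 2372 reads against 5572 to 6552 in wild-type. Its mean log2 value was 5.05 ± 0.16 (SD, n = 4) in null and 6.53 ± 0.19 (SD, n = 3) in wild-type tissue. Smchd1, on chromosome 17 from 71344489 to 71475343 in mm10, fell by 1.48 on the log2 scale (SE 0.13, limma adjusted p = 0.000238), to 0.359 of the wild-type level. The centred change fell by 1.67 (adjusted p = 9.54e-05). The transcript thus remained measurable in all 4 null libraries.

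On the deposited scale 5 genes rose and 1 gene, Smchd1, fell at an adjusted p under 0.05. Vmn1r90, named for the vomeronasal receptor family, rose by 2.29 (SE 0.21, limma adjusted p = 0.000244), from 124 to 206 reads in wild-type to 724 to 772 in null libraries. Its centred change was 2.10 (adjusted p = 0.000728). The row spans chromosome 7 from 14530654 to 14623066, and whether reads of related family members were counted in it was not examined. Malat1, a nuclear long noncoding RNA on chromosome 19, rose by 0.98 (SE 0.12, limma adjusted p = 0.0091), with a centred change of 0.79. Ccng1, a p53 target that encodes cyclin G1, rose by 0.84 (SE 0.11, limma adjusted p = 0.00933), with a centred change of 0.65. The X-linked p53 target Eda2r rose by 1.28 (SE 0.20, limma adjusted p = 0.0414), with a centred change of 1.09. The fifth gene, 4930433N12Rik, had a mean below the limit of the naming rule and was named after its values were seen. Its log2 change was 3.40 (limma adjusted p = 0.0224), with a centred change of 3.20. Every wild-type value of this gene lay below the filter limit, with 5 to 22 reads against 99 to 160 in null libraries. After centring, Smchd1 and Vmn1r90 passed, whereas Malat1 (adjusted p = 0.144), Ccng1 (adjusted p = 0.103), Eda2r (adjusted p = 0.207) and 4930433N12Rik (adjusted p = 0.103) did not. After centring, Malat1, Ccng1 and Eda2r still lay higher in every null library than in every wild-type library. So did 4930433N12Rik, which the filter kept through the null libraries alone. At an unadjusted p under 0.05, 1948 genes were higher and 16 lower on the deposited scale, against 1020 higher and 939 lower after centring. On the deposited scale the count of higher genes depended on single libraries: it was 4218 without wild-type library A, 164 without null library A, 100 without wild-type library B, 3 without null library B and 1 without wild-type library C. The median log2 value of kept genes was 4.19 in wild-type library A, against 3.85 in B and 3.77 in C. Without wild-type library A, all calls numbered 4220 as deposited but 4 after centring. Deposited-scale counts without that library therefore largely reflect library scaling. Without wild-type library C, the adjusted p was 0.0747 for Malat1, 0.0602 for Ccng1, 0.17 for 4930433N12Rik and 0.453 for Eda2r; without null library B it was 0.0614 for Ccng1 and 0.0715 for Eda2r, and without null library D 0.0503 for Eda2r.

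**Figure D1:**
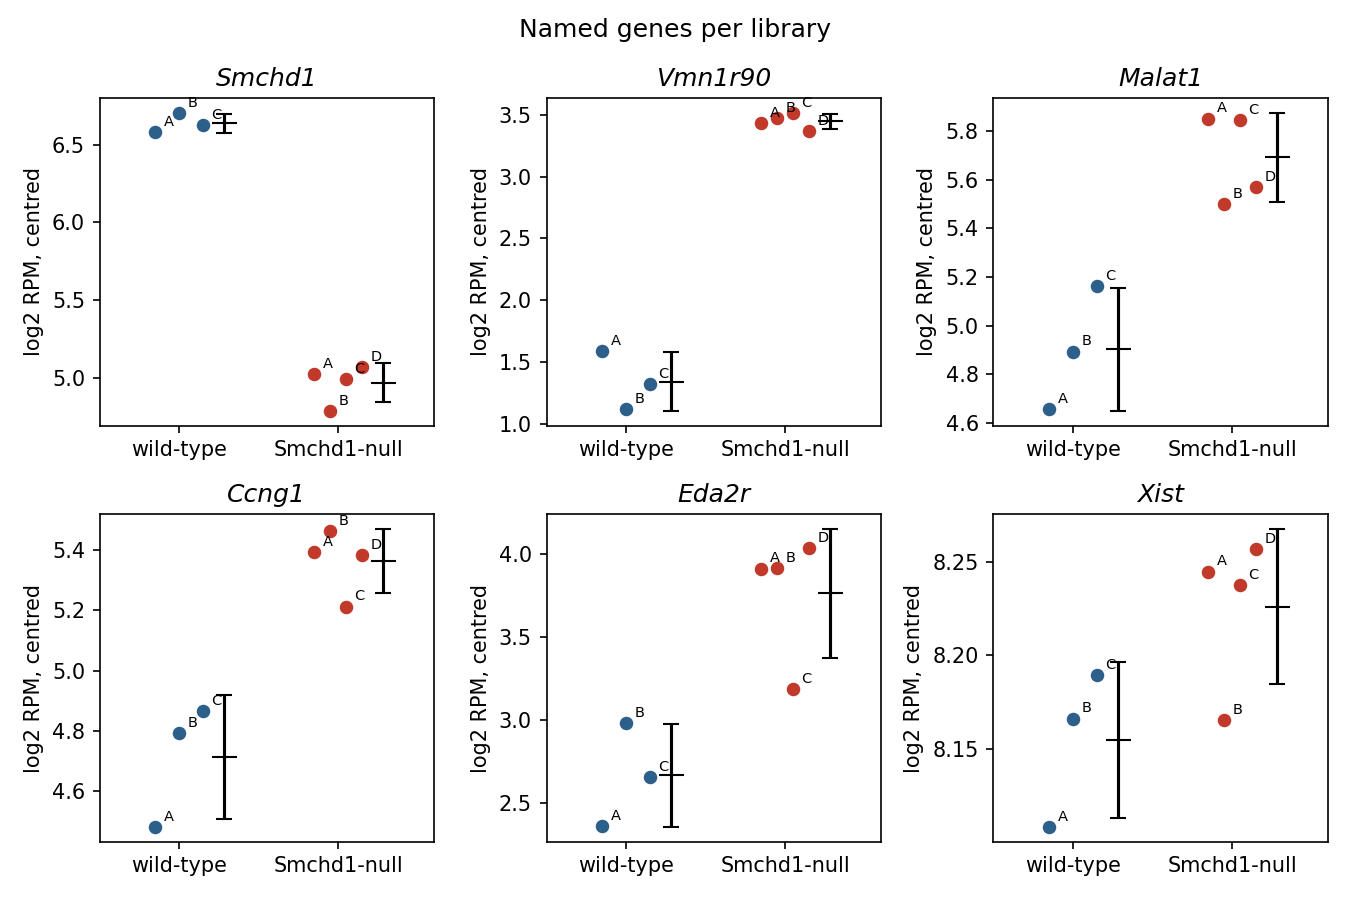
Centred log2 RPM of 6 genes in each lettered library, for wild-type (n = 3, blue) and Smchd1-null (n = 4, red), with black bars for the group mean and SD. Smchd1 lies lower and Vmn1r90 higher in all 4 null libraries than in all 3 wild-type libraries, while the groups overlap for Xist.

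X-linked genes were higher in null tissue as a group. The mean log2 value of X-linked genes minus that of autosomal genes was -0.09 ± 0.03 (SD, n = 4) in null and -0.24 ± 0.05 (SD, n = 3) in wild-type libraries. The difference of 0.15, or 1.11-fold, gave p = 0.0286 in a two-sided exact permutation test over 35 splits, the smallest p this design allows. After centring, 360 of 495 X-linked genes (72.7%, with Xist left out) had a fold change above 0, against 41.4% of 13500 autosomal genes. In 161 X-linked genes every null library lay above every wild-type library, which was 32.5% of them, against 5.56% of autosomal genes and 2.86% by chance. Another 6 X-linked genes lay lower in every null library. Leaving out the listed genes that escape X inactivation gave a difference of 0.15. With no filter on low values the difference was 0.03, with an exact permutation p = 0.314, and camera called 0 chromosomes.

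The number of single X-linked genes called depended on the processing. On the deposited scale 1 X-linked gene was called, with 18 under the stricter filter and 17 with a robust prior. After scaling, 6 were called with centring, 17 with cyclic loess and 14 with quantile normalization. On the deposited scale the count was 289 without wild-type library A, 24 without null library A, 20 without wild-type library B, and 0 without null library B, null library D or wild-type library C. The 6 were named after their values were seen. Taf1, a subunit of the general transcription factor TFIID, had a centred change of 0.52 (limma adjusted p = 0.00123), and Ogt, the O-GlcNAc transferase, 0.50 (adjusted p = 0.00123). The mitochondrial cardiolipin gene Taz reached 0.65 (adjusted p = 0.00866) and Araf, a RAF family kinase, 0.48 (adjusted p = 0.011). Med12, a Mediator subunit, reached 0.43 (adjusted p = 0.011) and Atp6ap1, an accessory subunit of the vacuolar ATPase, 0.43 (adjusted p = 0.0258). Xist, the noncoding RNA that coats the inactive X, had a change of 0.26 (adjusted p = 0.298) and a centred change of 0.07 (adjusted p = 0.385). Reads of Xist and its antisense partner Tsix differed by at most 18 in any library, so the values of these 2 genes cannot be told apart.

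Among the chromosomes tested by camera, only the X chromosome passed, on the deposited scale (adjusted p = 3.04e-14) and after centring (adjusted p = 5.04e-19). With an estimated correlation, the deposited scale gave an adjusted p = 0.996 and the centred scale an adjusted p = 0.00205. The planned Fisher's exact tests on called genes treat genes as independent. For X-linked against autosomal genes among the higher calls, Fisher's p was 0.165 as deposited and 1.31e-08 after centring. Per chromosome, Fisher's test passed for none on the deposited scale and for the X alone after centring (adjusted p = 1.01e-06). Of the 20-Mb windows along the X, the one from 40 to 60 Mb had a mean centred change of 0.35 over 52 genes, and the one from 80 to 100 Mb 0.03 over 33 genes. The libraries of the groups did not overlap (exact permutation p = 0.0286) except from 80 to 100 Mb (p = 0.657) and from 160 to 180 Mb (p = 0.114). Differences between windows were not tested.

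**Figure D2:**
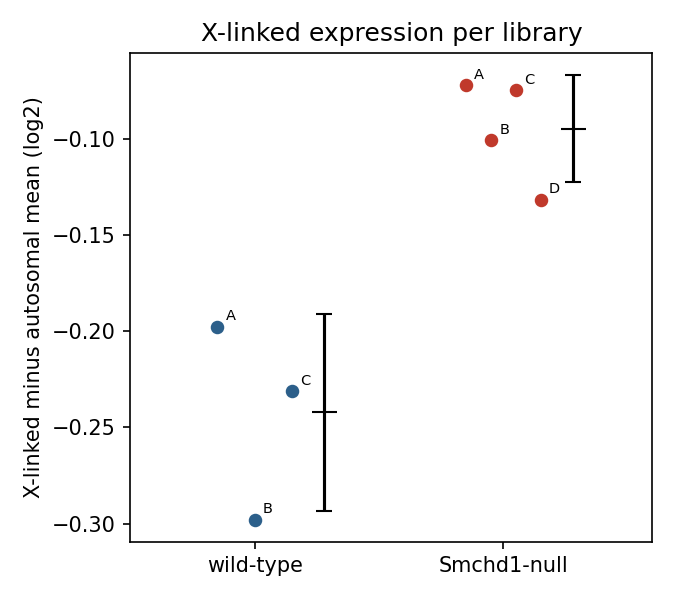
Mean log2 value of X-linked minus autosomal genes in each lettered library, for wild-type (n = 3, blue) and Smchd1-null (n = 4, red), with black bars for the group mean and SD. All 4 null libraries lie above all 3 wild-type libraries.

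**Figure D3:**
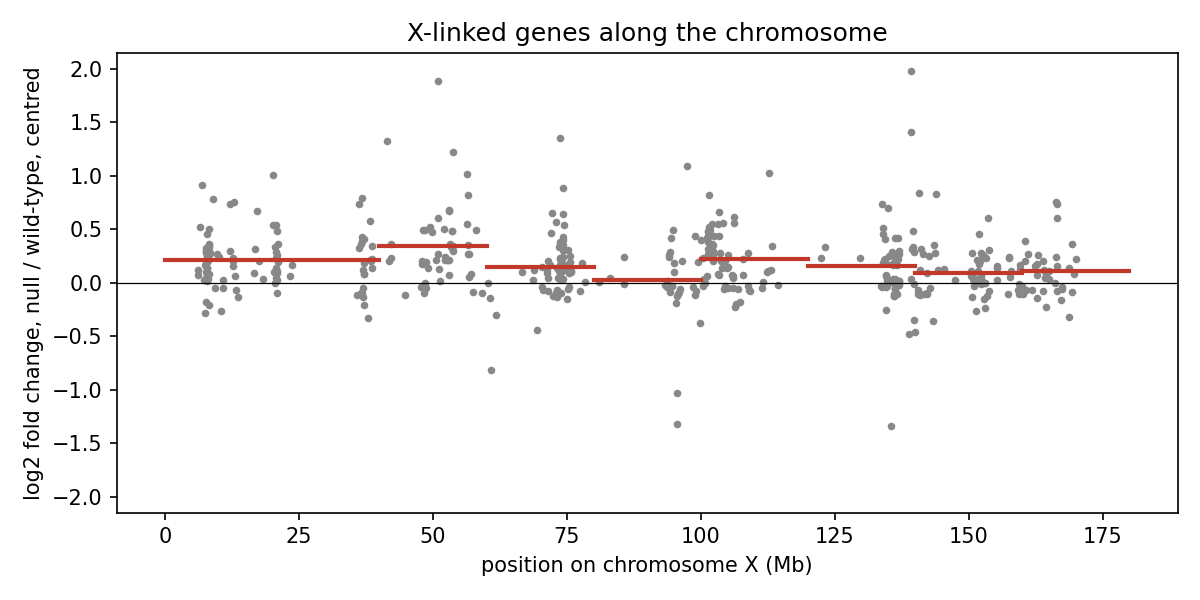
Centred log2 fold change of each X-linked gene (grey points) against its start position in Mb, with red lines for the mean of each 20-Mb window. The window from 40 to 60 Mb has the mean of 0.35, and that from 80 to 100 Mb 0.03.

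Genes of the p53 response were higher in null tissue as a list by camera at the preset correlation. Of 25 measured members 2 rose over all genes, Ccng1 and Eda2r, and 10 when adjusted over the list alone, with none lower. The latter included Cdkn1a, the cell-cycle inhibitor p21 (log2 change 1.16, centred 0.97, limma adjusted p = 0.00172 over the list), and Trp53inp1 (0.82, centred 0.63, adjusted p = 0.00513). After centring 0 passed over all genes and 6 adjusted over the list alone. The count adjusted over the list alone was 18 without wild-type library A, and after centring 3 without null library B or D and 2 without wild-type library A. The list mean lay 0.23 above the autosomal mean (camera adjusted p = 9.56e-08; centred adjusted p = 4.81e-05), with an adjusted p = 0.33 with an estimated correlation and 0.288 after centring. Per library the centred list mean was 0.26 higher in null tissue, with an exact permutation p = 0.0571, or 0.263 adjusted over lists.

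Markers of the notochord and hindgut, which the dissected piece could hold, were higher together by camera at the preset correlation. No member of either list passed over all genes. Adjusted over the list alone, 5 of 10 notochord genes rose, among them Noto (1.23, centred 1.04, limma adjusted p = 0.0011) and Chrd (1.00, centred 0.81, adjusted p = 0.0011), and 3 after centring. Of 10 hindgut genes 8 rose on that basis, including Foxa2 (0.82, centred 0.62, limma adjusted p = 0.00711) and Cdh1 (0.81, centred 0.62, adjusted p = 0.0109), and 1 after centring. Foxa2 belongs to both lists. The camera adjusted p was 2.9e-05 for notochord and 0.000181 for hindgut, and 0.000305 for each after centring. With an estimated correlation the adjusted p = 0.315 for each, and 0.288 after centring. The exact permutation p over libraries was 0.0571 for each, or 0.263 adjusted over lists. Without wild-type library A the deposited scale gave a camera adjusted p = 0.251 for notochord and 0.19 for hindgut. Without wild-type library B, Cdh1 had a change of 0.47 (centred 0.32), and 5 hindgut genes rose adjusted over the list alone, against 4 without wild-type library C and 5 without null library C. After centring the hindgut count was 7 without wild-type library C, 3 without wild-type library B and 2 without wild-type library A. The notochord count on that basis was 3 without null library B and 9 without null library A or wild-type library A.

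Clustered Hox genes, which pattern the body axis, did not pass as single genes. None of the 38 measured members passed over all genes or adjusted over the list alone, and the camera adjusted p was 0.188. On the deposited scale the members passing over the list alone were 7 without null library A, 17 without wild-type library A and 1 without wild-type library B. The list passed camera without null library A (adjusted p = 0.0365), null library C (0.0059) or wild-type library B (0.0104). The list mean lay 0.26 above the autosomal mean, and the median 0.06 above the autosomal median. Paralogue groups 9 to 13 had a list mean 0.75 above the autosomal mean (camera adjusted p = 0.0252; adjusted p = 0.825 with an estimated correlation; centred adjusted p = 0.0574), and groups 1 to 8 did not pass (camera adjusted p = 0.979, toward higher values, with a list mean of -0.06, or 0.03 without wild-type library B). Hoxc13 had a log2 change of 2.48 (centred 2.29, SE 0.88, limma adjusted p = 0.267), Hoxd12 3.25 (centred 3.06, SE 1.24, adjusted p = 0.292) and Hoxa7 0.35 (centred 0.16, adjusted p = 0.224). Without wild-type library B, which had 3 reads of Hoxc13 and 4 of Hoxd12, their changes were 1.02 (centred 0.87) and 1.22 (centred 1.07). The list mean of groups 9 to 13 was then 0.18 (camera adjusted p = 0.00662; centred adjusted p = 0.334), and without wild-type library A it was 1.05 (adjusted p = 0.44). The mean of groups 9 to 13 minus that of groups 1 to 8 was -0.60 ± 0.57 (SD, n = 4) in null and -1.41 ± 1.15 (SD, n = 3) in wild-type libraries, with an exact permutation p = 0.286. Wild-type library B had the lowest mean of groups 9 to 13, at -1.19 relative to the wild-type mean, and Cyp26a1, which degrades retinoic acid in the tailbud, had 200 reads there against 2033 to 3100 in the others.

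Other gene groups known from studies of Smchd1 were also measured. Of 58 listed clustered protocadherins, which encode neuronal adhesion proteins, 24 were in the table and 4 passed the filter. Of the 4, 3 rose when adjusted over the list alone, on both scales, and 0 over all genes: Pcdhb22 (1.61, centred 1.42, limma adjusted p = 0.000827), Pcdhb19 (1.52, centred 1.33, adjusted p = 0.00383) and Pcdhac1 (0.99, centred 0.79, adjusted p = 0.00383). In Pcdhb22 and Pcdhb19 every wild-type value lay below the filter limit, so these 2 were kept through the null libraries alone, and the camera adjusted p of the 4 rows (0.000151; centred 0.00247; adjusted p = 0.315 and, centred, 0.288 with an estimated correlation) rests on rows selected in this way. Over all 24 rows with no filter, 22 had a centred fold change above 0, and 15 were higher and 0 lower adjusted over the list alone. Their camera adjusted p was 4.97e-14, or an adjusted p = 0.416 with an estimated correlation, an alternative chosen after seeing the data. The exact permutation p over libraries was 0.0286 for the 24 rows, which is unadjusted and the smallest that this design allows. For the 4 filtered rows it was also 0.0286, or 0.263 adjusted over lists. No list passed this permutation test once adjusted over lists. In the imprinted clusters around Snrpn and Igf2r, 3 of 10 genes rose adjusted over the list alone, on both scales, and 0 over all genes. These were Mkrn3 (1.40, centred 1.21, limma adjusted p = 0.000378), Peg12 (0.78, centred 0.59, adjusted p = 0.000378) and Ndn (0.51, centred 0.32, adjusted p = 0.00293), all in the Snrpn cluster. That list had a camera adjusted p = 0.0415, which was 0.825 with an estimated correlation and 0.0825 after centring. Its mean of 0.17 above the autosomal mean was 0.07 without null library A (camera adjusted p = 0.306), 0.11 without null library C (0.0999), 0.22 without wild-type library A (0.18) and 0.28 without null library D (0.000136). Adjusted over the list alone, 7 genes rose without wild-type library A. Of 43 other imprinted genes 0 passed on either basis. Camera called them lower than the other genes at adjusted p = 0.044 (0.272 after centring, and 0.827 with an estimated correlation), although their mean log2 change was 0.12. That call was lost without null library A, B or D or wild-type library A or C (camera adjusted p = 0.0685, 0.202, 0.215, 0.131 and 0.29), and without wild-type library A 16 members were higher adjusted over the list alone.

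**Figure D4:**
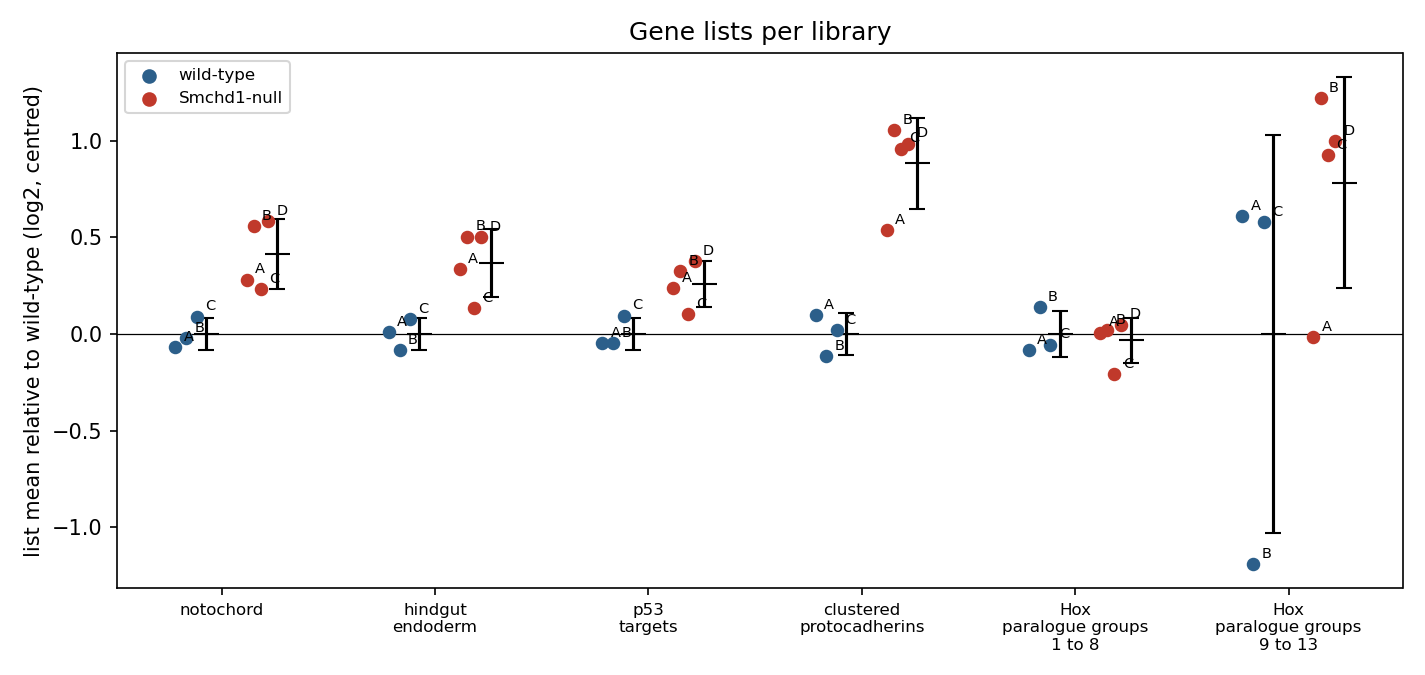
Centred mean log2 value of 6 gene lists in each lettered library, relative to the wild-type mean of the list, for wild-type (n = 3, blue) and Smchd1-null (n = 4, red), with black bars for the group mean and SD. The notochord, hindgut, p53 and protocadherin (4 filtered rows) means lie higher in all 4 null libraries than in all 3 wild-type libraries, and the groups overlap for both Hox lists.

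Presomitic mesoderm and tailbud genes did not pass as a list (camera adjusted p = 0.289), with 0 of 25 called over all genes and 3 adjusted over the list alone. These were the X-linked Cdx4 (0.63, centred 0.44, limma adjusted p = 0.00584), T (0.76, centred 0.57, adjusted p = 0.0454) and Fgf4 (2.34, centred 2.15, adjusted p = 0.0484), none of which passed on that basis after centring except Cdx4. Without wild-type library B, T had a change of 0.41 (centred 0.26) and Fgf4 1.37 (centred 1.23). The count on that basis was 1 without null library B or wild-type library C, 13 without null library A and 14 without wild-type library A, and the list passed camera without null library C (adjusted p = 0.0468). The segmentation clock list had no member passing on either basis (camera adjusted p = 0.433), and 3 members were higher over the list alone without wild-type library A and 2 without null library A.

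Lists of neural tube, somite derivatives, lateral plate mesoderm and blood were lower than the other genes by camera on the deposited scale (adjusted p = 6.59e-07, 2.53e-05, 4.25e-09 and 0.00388). Their mean log2 changes there were -0.09, -0.09, -0.12 and 0.12, so blood genes were on average higher in null tissue, though less so than other genes. None of these 4 passed after centring (0.582, 0.483, 0.227 and 0.687) or with an estimated correlation (adjusted p = 0.328, 0.315, 0.328 and 0.825). Adjusted over the list alone, no member of them was lower, and 2 were higher, Elavl3 of the neural tube (1.46, centred 1.27, limma adjusted p = 0.019) and Pax2 of the lateral plate list (0.79, centred 0.59, adjusted p = 0.0465), neither of which passed after centring. Lower members on that basis numbered 5 in lateral plate and 4 in blood without wild-type library B, 3 in lateral plate without null library C, and 2 in somite derivatives without null library A or D. They numbered 1 in somite derivatives without wild-type library B or C and 1 in lateral plate without null library A, and 1 there after centring without wild-type library A. Higher members numbered 2 in somite derivatives without null library A, null library C or wild-type library B. Elavl3 did not pass without wild-type library A or C, and Pax2 without null library B or D or wild-type library C. By camera the neural tube and somite lists did not pass without wild-type library B (adjusted p = 0.614 and 0.261), nor blood without null library C, null library D or wild-type library C (0.129, 0.255 and 0.0983). Relative to the autosomal mean, the lateral plate mean of -0.35 was -0.21 without null library B and -0.17 without null library D. The neural tube mean lay above the autosomal mean, by 0.04, without wild-type library B, and the blood mean by 0.29 without wild-type library C and by 0.01 without null library D.

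Surface ectoderm (camera adjusted p = 0.119), endothelium (0.263), hypoxia and glycolysis (0.0839), immediate early genes (0.0938) and retinoic acid and Gdf11 signalling (0.0938) did not pass. For the last 2 the list mean was above the autosomal mean, by 0.07 and 0.10, while camera pointed to lower values. Without wild-type library B the mean was -0.03 for immediate early genes, -0.07 for retinoic acid signalling and -0.10 for endothelium, and without null library D it was -0.06 for hypoxia and glycolysis. Without wild-type library C the retinoic acid mean was 0.20 and the immediate early mean 0.25. Of these 5, surface ectoderm passed without null library D (camera adjusted p = 0.0149) or wild-type library C (0.0144), and endothelium without null library D (0.00407) or wild-type library C (0.0413). Hypoxia and glycolysis passed without any 1 library except null library D (camera adjusted p from 2.37e-08 to 0.0468, and 0.343 without null library D). Immediate early genes (3.96e-06) and retinoic acid signalling (0.0427) passed without wild-type library A. None of the 5 had a member passing adjusted over the list alone, but without wild-type library A 8 endothelium and 5 surface ectoderm genes were higher, and without null library C 10 of hypoxia and glycolysis. Germline genes (0.361) and SMCHD1 partners and Polycomb components (0.695) did not pass either, and in the latter list Smchd1 alone was called over all genes. Adjusted over that list alone, 4 members were higher, Lrif1, listed as 4933421E11Rik (0.64, centred 0.45, limma adjusted p = 0.0395), Ezh1 (0.53, centred 0.33, adjusted p = 0.0475) and the X-linked Stag2 (0.42, centred 0.23, adjusted p = 0.0276) and Smc1a (0.36, centred 0.17, adjusted p = 0.0395), and all but Ezh1 also passed after centring. Without null library B, C or D or wild-type library B or C, 0 members were higher on that basis on the deposited scale, and 11 without wild-type library A; Stag2 passed after centring without each library in turn. The list of the X-inactivation centre and escape genes passed (adjusted p = 0.0018; centred 0.0152; adjusted p = 0.825 and, centred, 0.288 with an estimated correlation), with Shroom4 (0.72, centred 0.53, limma adjusted p = 0.00719) passing adjusted over the list alone, though not without wild-type library C (0.0808). Without wild-type library A 11 of its 13 members were higher on that basis, and after centring the list did not pass camera without null library A (adjusted p = 0.0731) or wild-type library A (0.0572). All members of this list are X-linked, so its camera result cannot be told apart from the shift of the whole X. The list mean lay 0.07 above the autosomal mean, against 0.15 for all X-linked genes. Its exact permutation p over libraries was 0.0571, or 0.263 adjusted over lists.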

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

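The tests of expression, length and GC bias were set out before their result was seen; the other tests weighed here were chosen after it. Among 89 values tested for a library far from the other null libraries, 4 stood apart, near the 4.4 that chance gives. Pax9 was at 1.52 in null library A, against 3.45 to 3.64 in the others. Nr4a1 was at 3.40 in null library D, against 2.44 to 2.54. Cyp26a1 was at 5.22 in null library A, against 5.50 to 5.55. The list mean of Hox groups 1 to 8 was -0.21 in null library C, against 0.01 to 0.05. Wild-type library C held 43 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, against 0 to 8 in the other libraries.

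The higher X-linked level in null tissue was weighed against technical sources. After correction of each library for expression level, exon length and GC content the difference was 0.15 on the log2 scale (0.149), with the groups still apart, which argues against these trends as its whole cause. Without wild-type library C it was 0.153 over the same genes, and Ddx3y there was 0.221% of Ddx3x, which argues against a trace of male tissue in that library as its source. Of 35 splits of the libraries only 1, the real one, gave as large a camera statistic for the X chromosome over the filtered genes, at -log10 p of 14.8 against 13.1 for the highest other split. These are the same splits as in the exact permutation test, used after the groups were seen to lie apart, so this count adds no independent evidence against chance. With no filter on low values the X-linked difference was 0.0277 (exact permutation p = 0.314). A weaker silencing of the inactive X in null tissue may underlie the difference over the filtered genes, as a hypothesis, since a parental or allelic signal was not measured.

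Relative to the autosomal median the p53 targets were 0.261 higher in null libraries (exact permutation p = 0.0571, or 0.263 adjusted over lists). The groups lay barely apart, with the lowest null library at 3.73 and the highest wild-type library at 3.72. This argues only weakly against library scaling as the whole cause of the difference. Without the X-linked member, Eda2r, the difference over 24 genes was 0.227, and the groups then overlapped, with the lowest null library at 3.75 and the highest wild-type library at 3.77. The rule written for this test counted overlap as an outcome that the X-linked explanation predicts. By that rule the X-linked explanation is not excluded, although the difference was 0.227 without Eda2r against 0.261 with it. The exact permutation p without Eda2r was 0.0857. With X-linked genes left out, camera at the preset correlation on the deposited scale still passed (adjusted p = 3.68e-07). Immediate early and stress genes, a sign of handling, differed by 0.10 (0.1), with 2 SE reaching 0.598. Within each last number of the column name they differed by 0.12, 0.14 and 0.16, against 0.29, 0.28 and 0.26 for p53 targets, with an exact permutation p = 0.167 for both lists, so dissection stress cannot be told apart from a genotype effect with 7 libraries. A p53 response to loss of Smchd1 remains an untested hypothesis.

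The mean of Hox groups 9 to 13 differed between libraries. The last number of the column name, 18, 21 or 22, may mark developmental stage, which no label states. Within genotype the libraries numbered 21 or 22 were 1.42 higher than the library numbered 18, with an exact permutation p = 0.0833, the smallest of 12 arrangements; the numbers form separate clusters, so no correlation is given. Within numbers the null libraries were 0.68 higher (0.685; exact permutation p = 0.0833, again the smallest of 12), by 1.17 at number 18, which holds wild-type library B, 0.42 at 21 and 0.46 at 22. Stage and genotype therefore both stay open and cannot be told apart from chance in this design.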

How the results depend on the processing

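The alternatives with blocks on the column-name numbers, voom on recovered reads, and those combining centring with another choice, and the estimated correlation with no filter for protocadherins, were chosen after seeing the data. No paired analysis was possible because the numbers in the sample titles are not in the column names; blocks on the numbers that the column names do hold were run instead. Smchd1 kept its direction under every alternative. It stayed past the threshold (adjusted p from 1.31e-22 to 0.0291) under all but the block on the first number of the column name. Only the first number 4180 held both genotypes, with 1 null and 2 wild-type libraries. The genotype change under that block therefore rested on 1 null library, so only effect sizes are given for it. With that block Smchd1 fell by 1.22. The count of higher genes, 5 as reported, was 43 with the stricter filter, 11 with 1 RPM added, 18 after cyclic loess, 15 after quantile normalization, 52 with a robust prior, 2 without the prior trend, 3 with a minimum log2 change of 1, and 11 by voom on recovered reads. It was 698 with a block on the last number of the column name, and 8789 with array weights, whose estimation did not converge. The array weight was 28.9 for wild-type library B, against 0.101 for A and 0.198 for C, so that fit rested mostly on 1 wild-type library. Leaving out each library in turn gave 1 to 4218 higher and 1 to 46 lower genes. Lower genes, 1 as reported, numbered 401 with array weights and 44 with the block on the last number. X-linked higher genes, 1 as reported, numbered 0 with no filter, 18 with the stricter filter, 4 with 1 RPM added, 6 after centring, 17 after cyclic loess and 14 after quantile normalization. They numbered 17 with a robust prior, 0 without the prior trend, 410 with array weights, 81 with the block on the last number and 10 by voom. Leaving out each library gave 0 to 289 of them. After centring, leaving out null library A, B, C or D gave 5, 2, 5 or 3 X-linked genes, and leaving out wild-type library A, B or C gave 2, 6 or 2. Centring with a robust prior and centring with the block on the last number gave 6 each. Higher genes after centring numbered 3 without null library B, 3 without wild-type library A, 9 without wild-type library B and 3 without wild-type library C. The X-linked shift of 0.15 was 0.0277 with no filter (exact permutation p = 0.314) and 0.12 to 0.17 without each library, where the smallest exact p is above 0.05. Chromosomes called numbered 0 with no filter, 0 with an estimated correlation on the deposited scale and, by construction, 0 without X-linked genes. After centring, the X passed with an estimated correlation (camera adjusted p = 0.00205). Lists called, 12 as reported, numbered 5 after centring, 6 after cyclic loess, 0 with an estimated correlation on the deposited and on the centred scale (0), 4 by fry and 6 by voom, and after centring 5, 6, 11 and 8 without null library A, B, C and D and 6, 8 and 12 without wild-type library A, B and C. The Hox list, at 0.26, passed with no filter (0.29), after quantile normalization (0.26), with the block on the last number (0.23), after centring without null library C (0.23) and in some fits without a library (0.0904 to 0.351). Some lists changed sign: immediate early genes to -0.0709 with the stricter filter and, leaving out each library, to a range of -0.0311 (without wild-type library B) to 0.246; Snrpn and Igf2r imprinted genes to -0.10, neural tube to 0.29 and somite derivatives to 0.0286 with the block on the first number; neural tube to 0.0371 without wild-type library B on both scales, within a range of -0.59 to 0.0371; and blood to 0.77 with array weights, 0.00963 without null library D and 0.287 without wild-type library C on both scales, within a range of -0.522 to 0.287. Lists that did not pass also turned without a library: endothelium to -0.102 and retinoic acid signalling to -0.0741 without wild-type library B, hypoxia and glycolysis to -0.0592 without null library D, and Hox groups 1 to 8 to 0.0305 without wild-type library B and 0.000406 without null library C. The large count of single genes without wild-type library A went with library scaling, with 4220 calls as deposited and 4 after centring. The cause of the other differences was not tested.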

Other observations

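These counts over other splits of the libraries were chosen after the results were seen. On the deposited scale 1 of 35 splits, the real one, gave 6 or more genes, and the highest other split gave 2. After centring 1 of 35 splits gave 8 or more genes, and the highest other split gave 1. For the gene lists, 15 of 35 splits called as many as the real 12, and the highest other split called 15, so chance cannot be excluded for the number of lists called by camera.

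Within the libraries of the same last number in the column name, the X-linked shift was higher in null tissue by 0.23 at number 18, 0.10 at 21 and 0.11 at 22. Among the libraries whose first number was 4180, 1 null and 2 wild-type, it was higher by 0.13 in null tissue. These differences have no replicate in at least 1 group and were not tested.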
